A study of Mus musculus with 6 samples.

How the data were processed

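Gene expression was measured by RNA sequencing in muscle stem cells of 10-week-old mice, taken 60 h after injury with cardiotoxin (CTX), a snake venom toxin that kills muscle fibres and starts their regeneration. The 6 libraries form 2 groups of 3. The control mice were labelled wild type and received oil, and the knockout (KO) mice were labelled as lacking Setdb1 and received tamoxifen, a drug used to activate inducible recombinases. Tamoxifen and genotype therefore changed together, and their effects cannot be separated in this design. The labels call the libraries of a group biological replicates, and the replicate numbers were taken from the labels.

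Per the labels' protocols, ribosomal RNA was removed from 400 ng of total RNA with a Ribo-Zero Gold kit, libraries were made with a stranded TruSeq total RNA kit, and paired reads of 75 bases were sequenced on a NextSeq500. The same labels also name a SMARTER mRNA-seq kit, so the kit of these libraries is not settled by the sources used here. Per the submitters' processing notes, STAR, Salmon and DESeq2 1.34.0 were used with the GRCm38 genome. Which of these tools counted the reads, the strand setting and the annotation release are not given in the sources used here. The authors deposited whole-number counts per Ensembl gene, not normalised, in 1 table with a column for each library, and whether these were rounded Salmon estimates could not be told from whole numbers. All 6 columns were used.

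The table held 55487 genes, of which 55141 were given a symbol from a table of Ensembl gene names, and the 346 others held 0.03% of the counts. Coordinates and gene types came from GENCODE release M21 on GRCm38. Total counts per library ran from 4052569 to 5690844. A single ribosomal RNA gene, CT010467.1, took 28.6% to 38.4% of the counts, so protein-coding genes received between 2002124 and 3050460 counts per library, and genes near 1 CPM (counts scaled by library size) rest on few reads. No molecular identifiers are named in the labels, so duplicate reads cannot be told from separate molecules. Intervals and floors of count ratios treat each count as independent and use counts summed over libraries. They cover counting error only, and not the spread between animals. Any 2 libraries of a group differed by more than sampling noise and none was a copy of another.

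Counts were tested with edgeR 4.0.16 (quasi-likelihood fit with robust dispersion, TMM normalisation, default low-count filter) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 11224 genes kept and a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. CPM values are normalised by TMM and given as mean ± SD over 3 libraries. Gene lists for pathways, gene families and cell types were fixed before the data were examined, and the 24 of 30 lists with at least 5 tested members were tested with camera in edgeR and limma 3.58.1 (preset inter-gene correlation of 0.01, adjusted over the lists). An estimated correlation and the fry test were alternatives. Genes named in the text were chosen by a rule also fixed before the data were examined. It took Setdb1, the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap and whose mean was at least 1 CPM (predicted genes, numbered clones, pseudogene symbols and genes without a symbol left out), the 5 smallest p-values per direction, up to 4 passing members of each list or, where none passed, the 2 with the highest level, and 8 genes named in advance. A few genes outside it are marked as chosen after their values were seen.

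The procedure was tested on 10 simulated data sets for the Setdb1 KO against control comparison, each with 200 changed genes. It recovered 15.4% of the genes changed 1.5-fold, 63.7% of those changed 2-fold and 92.9% of those changed 4-fold, and 8.3% of all calls were false. Sets with no change gave a mean of 2.7 calls. Many changes of less than 2-fold were thus out of reach at this depth and number of libraries.

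Alternatives were DESeq2 size factors within edgeR, upper quartile factors, library totals alone, no low-count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0 with its Wald test, limma-voom, the replicate number as a block, a test against a 1.2-fold change, removal of mitochondrial and structural RNA genes, and each replicate left out in turn. A term for granulocyte transcripts and the removal of control library 3 and KO library 1 together were chosen after seeing the data. Sequence shared between genes was measured as the percent of 50-base words of a gene's annotated transcripts found in annotated transcripts of any other gene, and overlap of exons with bedtools 2.31.1. Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.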

Results

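The comparison asked how the transcripts of muscle stem cells, the resident precursors that rebuild muscle fibres after injury, differed when Setdb1 was deleted. Setdb1 encodes an enzyme that methylates lysine 9 of histone H3, a mark of silenced chromatin. Cells of 3 control and 3 KO mice were compared 60 h after cardiotoxin. Control libraries held 4568845, 4716006 and 5690844 counts, and KO libraries held 4052569, 4909787 and 5178823.

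Setdb1 itself (ENSMUSG00000015697, chromosome 3, 95323525 to 95357202, minus strand, GRCm38) was measured at 34.9, 40.5 and 32.1 CPM in the control libraries and at 16.5, 12.7 and 14.7 CPM in the KO libraries. Its level fell from 35.8 ± 4.26 to 14.6 ± 1.88 CPM (mean ± SD, n = 3 each), a log2 fold change of -1.30 (SE 0.16, adjusted p = 2.092e-04). The deleted exon is not named in the labels, so counts from exons left in place can remain in this value.

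Loss of Setdb1 was accompanied mainly by increases. Of 11224 genes tested, 318 changed, of which 249 were higher and 69 lower in KO cells. At least 2-fold changes were seen in 145 of the higher and 13 of the lower genes. The 5 most significant increases were in Gsta4, Tnfrsf22, Tnfrsf23, Resf1 and Dop1b. Gsta4, a glutathione transferase (chromosome 9, 78182774 to 78209349), rose from 1.84 ± 0.73 to 98.1 ± 15.1 CPM (log2 fold change 5.72, SE 0.22, adjusted p = 3.155e-09). Resf1 (chromosome 6, 149309414 to 149335663), whose product acts in the silencing of retroelements, rose from 199 ± 7.17 to 949 ± 56.9 CPM (log2 fold change 2.25, SE 0.13). Tnfrsf22 and Tnfrsf23, adjacent genes for decoy death receptors on chromosome 7, rose by log2 fold changes of 2.92 and 3.48, to 64.8 ± 1.14 and 55.5 ± 4.46 CPM. They shared 27.4% and 18% of their 50-base words with other genes, so the division of reads between them is uncertain. Dop1b rose from 4.37 ± 1.04 to 41.8 ± 7.69 CPM.

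The largest increases among the genes the naming rule admits included genes with almost no control counts. Cck, the gene of the gut and brain hormone cholecystokinin, had 0 counts in all 3 control libraries and 54 in the KO libraries. This gave a ratio of 19.9 against a floor of 3 counts over the control group, with an exact 95% lower limit of 15.6. Wnt10b, a Wnt ligand gene, had 1 control count against 127 (ratio 140, 95% exact interval 24.7 to 5588). Tdrd9, a germline gene of the piRNA pathway, had 3 against 85 (ratio 31.3, interval 10.4 to 155). Tcfl5 rose by 4.70 on the log2 scale (SE 0.31), the transporter gene Slco1a5 by 3.91 (SE 0.33) and the carbonyl reductase gene Cbr3 by 3.79 (SE 0.27). The glutathione transferase genes Gstt1 and Gstt2, neighbours on chromosome 10, rose by 3.75 (SE 0.24) and 3.64 (SE 0.46). Gstt1 reached 86.9 ± 10.6 CPM from 6.36 ± 2.63. A larger change, chosen after its values were seen, lay outside the rule: Gm23804, a small nuclear RNA gene, had 0 counts in every control library and 2307, 1774 and 1887 in the KO libraries. The ratio against the same floor was 2199, with an exact 95% lower limit of 1788. Gm23804 shared 100% of its words with other genes, so the gene these reads came from is uncertain.

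Of the 69 genes that fell, Nptx1, a neuronal pentraxin gene (chromosome 11, 119538719 to 119547753), showed the largest decrease among those the naming rule admits. It fell from 18.4 ± 2.05 to 2.30 ± 0.56 CPM (log2 fold change -2.97, SE 0.24, adjusted p = 3.230e-06). Igfbp3, which encodes a binding protein for insulin-like growth factors, fell from 97.9 ± 2.22 to 33.0 ± 14.2 CPM. The Fanconi anaemia gene Fancb fell from 12.1 ± 2.40 to 4.24 ± 0.91 CPM. The chromatin protein gene Hmga2 fell from 127 ± 13.1 to 62.0 ± 6.94 CPM. The nuclear receptor gene Nr2f2 fell from 33.4 ± 2.42 to 17.5 ± 0.79 CPM. Rragb, Krt18, Rps6ka6, Zik1 and Ppm1l also fell, with log2 fold changes of -1.86, -1.32, -1.24, -1.16 and -1.04. Groups did not overlap in 24.3% of all tested genes, against the 10% that chance gives on average for 3 libraries against 3. This share was not measured for other splits of the libraries, so its spread is not known.

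**Figure D1:**
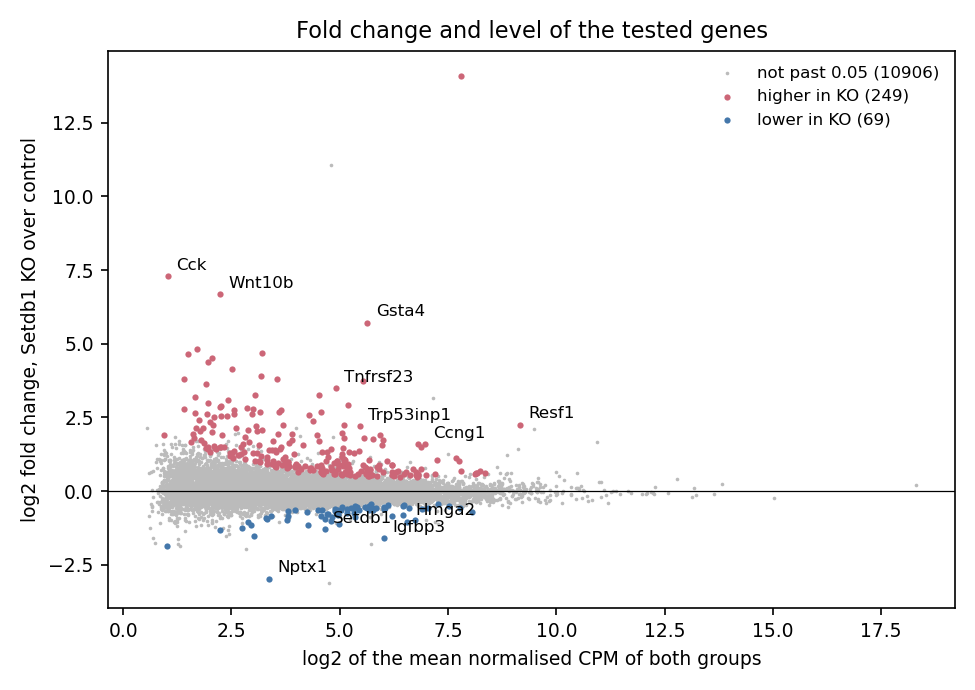
Log2 fold change (Setdb1 KO over control) of the 11224 tested genes against the log2 of their mean normalised CPM over both groups, n = 3 libraries per group. Red points are the 249 genes higher and blue points the 69 genes lower in KO cells at an adjusted p under 0.05, and the topmost red point is Gm23804.

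DESeq2 gave 184 changed genes, and leaving out 1 library gave 157 (142 higher, 15 lower) without control library 2, 152 (133 and 19) without KO library 1 and 180 (158 and 22) without KO library 2. Lower genes numbered 38 without control library 1, 43 without KO library 3 and 106 without control library 3 and KO library 1 together. The calls of Rragb and Ppm1l ended without any 1 of the 6 libraries (adjusted p up to 0.171 and 0.128). Those of Igfbp3 ended without control library 1, 2 or 3 or KO library 2 (up to 0.156), Krt18 without any but control library 1 (up to 0.131), Rps6ka6 without any but KO library 2 (up to 0.13) and Zik1 without any but control library 3 (up to 0.156). Of these genes, DESeq2 called Igfbp3 only.

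Targets of p53, the transcription factor activated by DNA damage, rose as a group. Of 33 tested members of the list of p53 targets and DNA damage response genes, 13 were higher and none lower (18 and 0 when adjusted over the list alone), with a median log2 fold change of 0.56 (camera adjusted p = 6.363e-18). This was the only list called with an estimated correlation as well (adjusted p = 0.047). Trp53inp1 rose from 15.7 ± 2.78 to 72.3 ± 5.52 CPM and the cyclin gene Ccng1 from 62.9 ± 0.72 to 189 ± 3.60 CPM. Mdm2, whose product degrades p53, rose from 99.2 ± 5.97 to 206 ± 24.0 CPM, and the epoxide hydrolase gene Ephx1 by a log2 fold change of 2.06 (SE 0.28). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 88.4 ± 5.66 to 148 ± 15.2 CPM (log2 fold change 0.74, SE 0.12, adjusted p = 0.002569). In the cell death machinery, Bax and Casp4 rose by 0.74 and 0.92 among 23 tested members (3 were higher and 0 lower when adjusted over the list alone). The list was not called (adjusted p = 0.089, and 0.353 with an estimated correlation), but it passed with fry, which does not compare it with other genes (adjusted p = 0.00711). The calls of Bax and Casp4 were not made by DESeq2 (adjusted p = 0.37 and 0.384) and ended without any 1 library but control library 3 (up to 0.189 and 0.16). Bax shared 8.5% of its words with other genes.

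Of 39 S phase genes, which act in DNA synthesis, none was higher and 3 were lower (0 and 18 when adjusted over the list alone), and DESeq2 called 1 lower. A negative fold change was measured in 38, and the median was -0.35 (camera adjusted p = 1.122e-10, but adjusted p = 0.237 with an estimated correlation). Tk1 fell from 29.4 ± 2.76 to 18.9 ± 2.27 CPM, Mcm10 from 43.2 ± 5.12 to 28.2 ± 3.82 CPM and Mcm7 from 179 ± 7.42 to 131 ± 6.61 CPM. No member of the list of G2 and M phase genes passed in edgeR, DESeq2 or limma-voom among 37 (0 when adjusted over the list alone, and 2 higher and 5 lower at an unadjusted p under 0.05; median -0.14, camera adjusted p = 0.043, and 0.841 with an estimated correlation). Mki67, the proliferation marker, was measured at 830 ± 45.6 and 689 ± 66.6 CPM (adjusted p = 0.302). No replication-dependent histone gene passed with these tools among 54 (0 when adjusted over the list alone, and 11 lower at an unadjusted p under 0.05; median -0.25, camera adjusted p = 5.957e-05, and 0.841 with an estimated correlation). The list of G2 and M phase genes was no longer called without control library 2, control library 3 or KO library 1 (adjusted p = 0.204, 0.0502 and 0.294), nor the histone list without control library 3 or KO library 3 (0.165 and 0.0751). The call of Mcm7, which shared 18.1% of its words with other genes, ended without any 1 library (adjusted p up to 0.147). That of Tk1 ended without any but KO library 1 (up to 0.141) and that of Mcm10 without any but control library 3 (up to 0.189), and DESeq2 made neither.

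Of 22 tested muscle differentiation genes, 5 were higher (3 with DESeq2) and none lower (8 and 0 when adjusted over the list alone; median 0.49, camera adjusted p = 2.698e-06, and 0.237 with an estimated correlation). Myod1, the transcription factor that commits cells to muscle, rose from 142 ± 5.50 to 292 ± 63.4 CPM (log2 fold change 1.04, SE 0.15, adjusted p = 7.791e-04). Lmod3 and Acta1, genes of the contractile apparatus, rose by 3.20 (SE 0.48) and 1.84 (SE 0.28), and Jsrp1 by 1.11 (SE 0.28), a call that DESeq2 did not make and that ended without any 1 library but control library 3 (adjusted p up to 0.186). Myog was measured at 3.88 ± 1.53 and 6.64 ± 2.32 CPM (adjusted p = 0.288). Of 8 mature myofibre genes, Actn3 rose by 0.76 (3 were higher when adjusted over the list alone; median 0.72, camera adjusted p = 0.0049, and 0.353 with an estimated correlation). The Actn3 call ended without KO library 1 (adjusted p = 0.065). Pax7, the marker of muscle stem cells, was at 26.9 ± 5.7 and 26.9 ± 6.56 CPM (log2 fold change -0.01, SE 0.19, adjusted p = 0.986). In the list of satellite cell markers, Sdc3 rose by 0.72 among 25 tested (1 higher when adjusted over the list alone; adjusted p = 0.286 for the list, and 0.888 with an estimated correlation). The list passed without control library 1 (adjusted p = 0.0147), and the Sdc3 call ended with DESeq2 and without control library 2 or KO library 1 (0.109 and 0.0898 for the libraries).

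**Figure D2:**
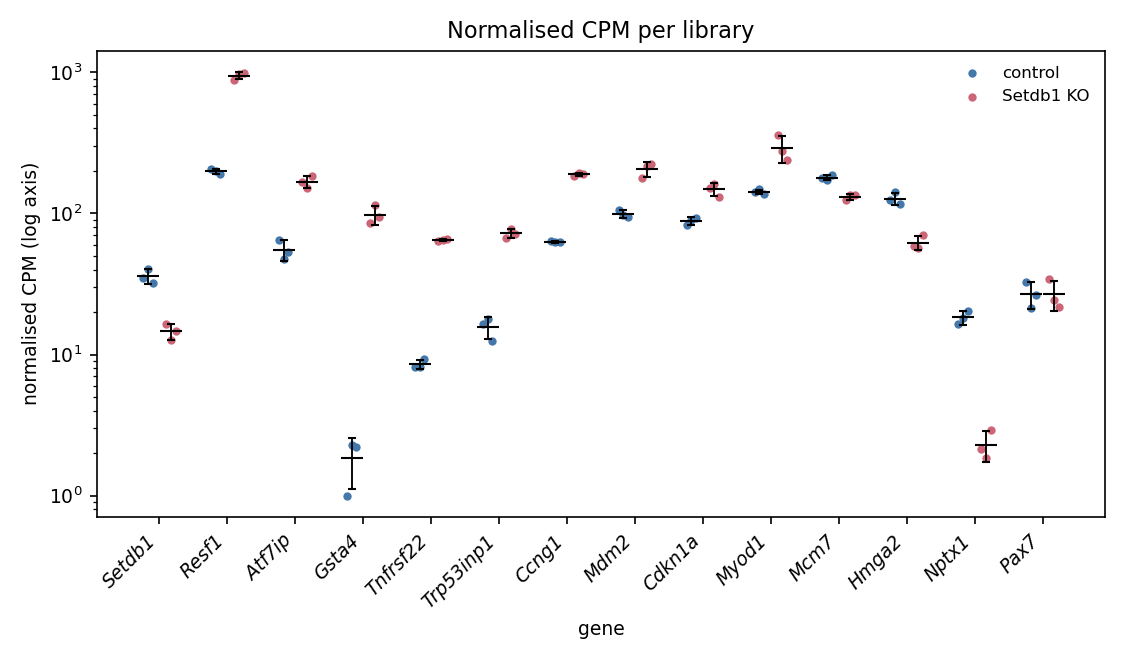
Normalised CPM (log axis) of 14 genes in each of the 3 control (blue) and 3 Setdb1 KO (red) libraries, with black bars for the mean and its SD. The groups do not overlap for any gene but Pax7, at 26.9 CPM in both groups.

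In the silencing machinery, the only gene called lower over all tested genes was Setdb1, the deleted gene, which was kept in the list and its test. Of 22 tested genes of the H3K9 methylation and silencing machinery, Resf1 and Atf7ip rose and Setdb1 fell (2 higher and 3 lower when adjusted over the list alone). Atf7ip, whose product binds SETDB1, rose from 55.3 ± 9.20 to 168 ± 16.2 CPM. The list was not called (median -0.25, adjusted p = 0.476, and 0.888 with an estimated correlation). Imprinted genes went both ways among 26 tested. Rian and Mirg, noncoding RNA genes of 1 cluster on chromosome 12, rose by 0.90 and 1.46, while Mest and Peg10 fell by 1.13 and 0.97 on the log2 scale (2 higher and 3 lower when adjusted over the list alone; list adjusted p = 0.794, and 0.888 with an estimated correlation). The Mirg call ended with DESeq2 (adjusted p = 0.394) and without any 1 library (up to 0.185), Rian without KO library 1 or 2 (0.105 and 0.054) and Peg10 without control library 1 or 2 or KO library 1 or 2 (up to 0.0697). Of 255 Zfp genes, 7 were higher and 0 lower (7 and 1 when adjusted over the list alone; list adjusted p = 0.824, and 0.888 with an estimated correlation). Among them were Zfp37, which rose by a log2 fold change of 2.70 (SE 0.24), Zfp52, and the adjacent Zfp955a and Zfp955b, which shared 51.8% and 31.4% of their words with other genes. The imprinted and Zfp lists had medians of -0.024 and -0.0037 with positive means, 0.0093 and 0.056, and a camera direction of down. Tdrd9 was the only germline gene with enough counts to test. Of the protocadherin beta genes only Pcdhb17 was tested (log2 fold change -0.14, adjusted p = 0.891). None of 8 clustered Hox genes passed in edgeR, DESeq2 or limma-voom (0 when adjusted over the list alone, and 4 lower at an unadjusted p under 0.05; median -0.46, list adjusted p = 0.052, and 0.353 with an estimated correlation). The Hox list passed without control library 1 (adjusted p = 0.0388).

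No interferon-stimulated gene passed in edgeR, DESeq2 or limma-voom among 24 tested (0 when adjusted over the list alone, and 4 higher at an unadjusted p under 0.05). A positive fold change was measured in 23, with a median of 0.33 (camera adjusted p = 0.0049, and 0.237 with an estimated correlation). Trim25 was at 25.1 ± 1.65 and 30.0 ± 0.54 CPM (adjusted p = 0.339). No nucleic acid sensing gene passed with these tools among 15 (0 when adjusted over the list alone, and 1 higher at an unadjusted p under 0.05; list adjusted p = 0.817, and 0.888 with an estimated correlation). Cgas and Tmem173, which encode the DNA sensor cGAS and its partner STING, had log2 fold changes of -0.20 (SE 0.25) and 0.26 (SE 0.26). No chemokine or cytokine gene passed in edgeR among 21 (2 higher and 1 lower when adjusted over the list alone, and 5 and 1 at an unadjusted p under 0.05; list adjusted p = 0.162, and 0.667 with an estimated correlation). DESeq2 and limma-voom each called 1 lower. Spp1 was at 560 ± 31.6 and 383 ± 66.8 CPM (adjusted p = 0.052). It passed without KO library 3 (0.0326) and the list without control library 3 (0.0331).

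**Figure D3:**
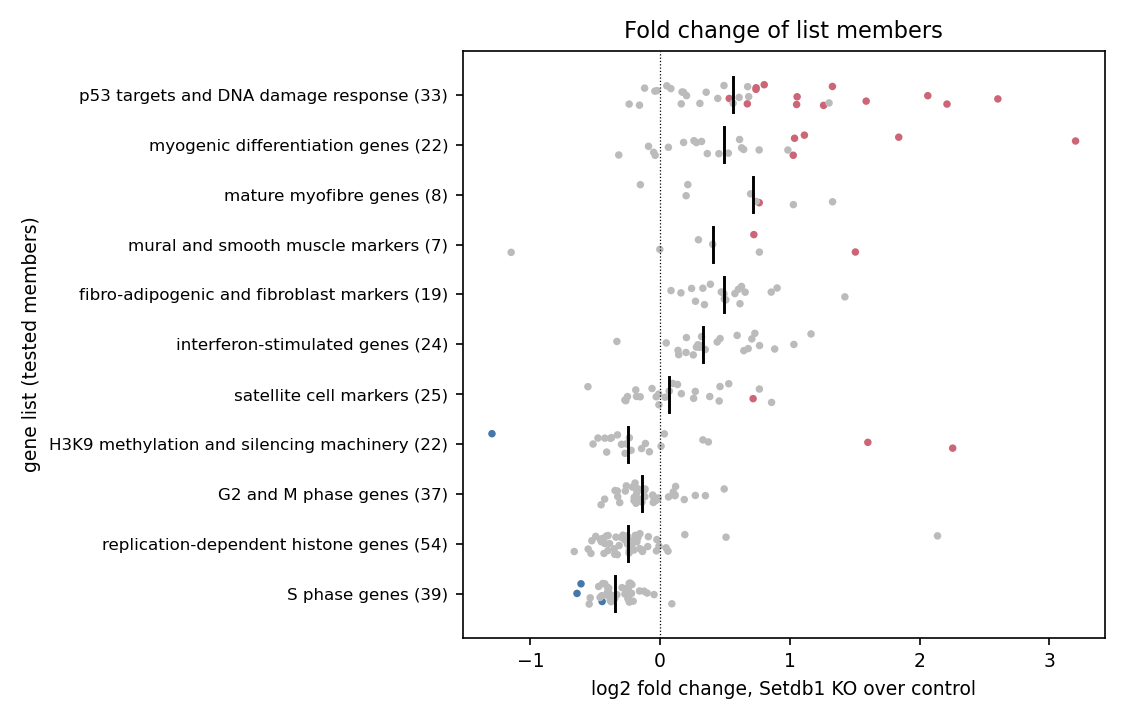
Log2 fold change (Setdb1 KO over control) of each tested member of 11 gene lists, n = 3 libraries per group. Red and blue points are members higher and lower at an adjusted p under 0.05 over all tested genes, grey points did not pass, and black bars are list medians, such as 0.56 for p53 targets and -0.35 for S phase genes.

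Markers of other cells in muscle were also measured. All 19 tested fibro-adipogenic and fibroblast markers had a positive fold change (median 0.49, camera adjusted p = 3.882e-04, and 0.667 with an estimated correlation). None passed in edgeR (3 higher when adjusted over the list alone, and 5 at an unadjusted p under 0.05), and DESeq2 and limma-voom each called 1 higher. Col1a1 was at 368 ± 187 and 548 ± 217 CPM (adjusted p = 0.633). Among 7 mural and smooth muscle markers, Tagln rose from 6.44 ± 1.95 to 18.5 ± 0.93 CPM, and Acta2 from 38.9 ± 7.21 to 64.4 ± 12.2 CPM (2 higher when adjusted over the list alone; camera adjusted p = 0.0049, and 0.353 with an estimated correlation). The Acta2 call ended with DESeq2 and without control library 1 or 2 or KO library 1 or 2 (adjusted p up to 0.161), and neither list was called without control library 2 (0.0629 for fibroblast and 0.0844 for mural markers). No tendon (10 tested, list adjusted p = 0.092), Schwann cell (5 tested, 0.813), macrophage (8 tested, 0.817) or neutrophil (6 tested, 0.813) marker passed in edgeR, DESeq2 or limma-voom, nor when adjusted over the list alone. In these lists, 2, 1, 0 and 0 members were higher at an unadjusted p under 0.05. The tendon list passed without control library 1, control library 3 or KO library 1 (adjusted p = 0.026, 0.0266 and 0.045), and the neutrophil list, upward, without control library 3 (0.0451) and without control library 3 and KO library 1 together (1.214e-12). The neutrophil list had a median of -1.02 and a camera direction of up. S100a9, an abundant neutrophil transcript, had 3406 counts in control library 3, 1051 in KO library 2 and 385 in KO library 3, and 0, 0 and 2 in control libraries 1 and 2 and KO library 1. Without control library 3, no control library left held S100a9. With KO library 1 removed as well, every KO library left held it, so the upward neutrophil call there was fixed by the choice of libraries. Ptprc, which marks blood cells, was at 3.88 ± 5.13 and 2.62 ± 0.99 CPM. Only 2 endothelial genes, Eng and Tek, and 1 erythroid gene, Bpgm, were tested, none of which passed with these tools or when adjusted over the list alone (1 endothelial gene at an unadjusted p under 0.05), and no lymphocyte gene was tested.

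No dissociation stress gene passed in edgeR among 26 (0 when adjusted over the list alone, and 8 higher and 2 lower at an unadjusted p under 0.05; list adjusted p = 0.055), and DESeq2 called 1. The list passed without control library 1, control library 3, KO library 1 or KO library 2 (adjusted p = 8.023e-04, 0.0458, 0.045 and 0.0447). No mitochondrially encoded gene passed in edgeR, DESeq2 or limma-voom among 25 (0 when adjusted over the list alone, and 3 higher at an unadjusted p under 0.05; list adjusted p = 0.794, median -0.062, mean 0.18, camera direction up). Of 82 genes in the list of ribosomal proteins, Rps4l, annotated as a transcribed processed pseudogene, rose from 1.51 ± 0.27 to 14.9 ± 2.38 CPM (1 higher when adjusted over the list alone; list adjusted p = 0.476, 0.00152 without control library 3, and 3.252e-05 without control library 3 and KO library 1 together). The Y-linked gene Ddx3y was at 44.4 ± 1.76 and 47.5 ± 5.39 CPM, and none of the 4 sex-linked genes tested passed in edgeR, DESeq2 or limma-voom (1 lower when adjusted over the list alone and at an unadjusted p under 0.05). Eif2s3y, also Y-linked, was at 23.6 ± 6.59 and 14.4 ± 3.44 CPM (adjusted p = 0.146, and 0.0181 without control library 3). Exons of Setdb1, Tcfl5, Tnfrsf23, Dop1b, Hmga2, Nr2f2, Mest, Atf7ip, Zfp52, Zfp955b, Cdkn1a, Sdc3, Tk1, Mcm7, Tagln, Cgas, Eng and Hist1h2ap overlapped a gene on the other strand. Strand use in counting is not given, and reads in these overlaps cannot be separated if strand was not used. Rps4l, Spp1 and Setdb1 shared 14.9%, 11.6% and 8% of their words with other genes.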

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

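A term for granulocyte transcripts and the joint removal of control library 3 and KO library 1 were chosen after seeing the data. The Setdb1 change stayed past the threshold in all 18 alternatives, from -1.46 to -1.21. Of 51 other named genes called, 33 passed in every alternative. Changed genes numbered 511 with no low-count filter, 184 with DESeq2 and 165 against a 1.2-fold change, genes higher 147 with DESeq2 and 148 against a 1.2-fold change, and genes lower 138 with no filter, 37 with DESeq2, 17 against a 1.2-fold change, 125 with the granulocyte term and 106 with both libraries removed. The wider sets of no filter and of DESeq2 had median log2 fold changes of 0.42 and 0.44, against 0.0074 for the 11224. With no filter 34908 genes were tested. DESeq2 gave an adjusted p to 14591, while its median covers every gene with a count. KO library 1 held counts in 30363 genes, against 18737 to 19951 in the others, so these medians cannot be read as a rise in all KO libraries. Of the 318 genes, 292 and 161 were called there too. With each replicate left out, changed genes ranged from 152 to 345, genes higher from 133 to 255, genes lower from 15 to 90 and called lists from 6 to 13. The estimated correlation left 1 called list of 9. Removing both libraries gave 394 changed genes and 14 called lists. S100a9 counts were then left in KO libraries only, so group and neutrophil transcripts changed together and cannot be separated in this setting. Besides macrophage, neutrophil and ribosomal protein lists, this removal called chemokines (adjusted p = 0.0404), tendon (0.014), dissociation stress (0.0267) and mitochondrial genes (0.0391), and it lost G2 and M phase genes (0.319) and histones (0.178). With fry, G2 and M phase genes (0.446), histones (0.496), fibroblast (0.268) and mural markers (0.0881) were lost and cell death was called. The granulocyte term called satellite markers (0.025), and the replicate block called Hox (0.0459), tendon (0.0356) and dissociation stress genes (0.0214). The 1.2-fold test asks for a larger change. Every removal left fewer libraries to test with, yet some removals raised the counts and some lowered them. The cause of these and of the other differences was not tested. Small changes were hard to detect at this depth and number of libraries, as 15.4% of simulated 1.5-fold changes were recovered. With the replicate number as a block, 41 genes were lower and 247 changed, but same-numbered libraries did not deviate together (correlations 0.142, -0.0925 and -0.0615), and the highest correlation, 0.286, joined control library 3 and KO library 2. A term for sex-linked genes was not run, since all 6 libraries held Y-linked transcripts and only control library 3 also held Xist above 8 counts.

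Of the 25 results that changed direction under some alternative, 17 genes and 8 lists, only macrophage markers passed the threshold where they did so, upward, with both libraries removed (adjusted p = 1.470e-04). In that setting only KO libraries held S100a9 counts, so this call cannot be read as an effect of Setdb1 loss. With both removed, log2 fold changes were 0.040 for Tbk1, 0.021 for Hist1h2ap, 1.84 for Lyz2, 12.49 for S100a9, 7.81 for Ngp, -0.056 for Ngfr and 0.10 for mt-Rnr1, and adjusted p was 0.655 for satellite markers. The granulocyte term gave -0.20 for Ly6c2, -0.081 for Ptn and 0.076 for Pax7, and adjusted p of 0.838 for Zfp genes, 0.13 for neutrophil markers, 0.823 for mitochondrial and 0.542 for ribosomal protein genes. With limma-voom, S100a9, Ngp and Ptprc were at 3.63, 1.92 and 0.24, with the replicate block S100a9 and Ngp at 1.08 and 0.94, with library totals Tek and Ngfr at -0.0032 and -1.228e-04, with upper quartile factors Pax7 at 0.0025, and with fry the Zfp list at 0.654. With each replicate left out, log2 fold changes ran from -0.28 to 0.059 for Pcdhb17, -0.43 to 0.044 for Hist1h2ap, -0.10 to 0.56 for Col1a2, -0.30 to 0.32 for Tek, -1.43 to 1.36 for Lyz2, -1.06 to 7.77 for Ly6c2, -2.43 to 11.85 for S100a9, -2.15 to 7.24 for Ngp, -0.11 to 0.24 for Ngfr, -0.23 to 0.53 for Ptn, -0.094 to 0.64 for Thbs4, -0.018 to 0.49 for Fmod, -0.042 to 0.16 for Klf6, -0.23 to 0.075 for mt-Rnr1, -1.09 to 1.48 for Ptprc and -0.21 to 0.15 for Pax7. Adjusted p ran from 0.165 to 0.907 for imprinted genes, 0.321 to 0.907 for Zfp genes, 0.677 to 0.979 for nucleic acid sensing, 0.0909 to 0.951 for macrophage markers, 0.0451 to 0.907 for neutrophil markers, 0.165 to 0.907 for mitochondrial genes and 0.00152 to 0.694 for ribosomal protein genes.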

Other observations

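The tests of where raised genes lie by chance, of uncalled neighbours, of shared reads as the whole cause, of Xist and Mpo, of receptor counts and of other splits of the libraries were chosen only after their results or the pattern had been seen. Glutathione transferase genes and protocadherin gamma genes were grouped after their values were seen. S100a8, Mpo, Elane, Prtn3, Xist, Cxcl13, Ccl21a, Hba-a1, Gm10800, Nnt, Ddt, Morc3, Fkbp11, Arf3, Gm16201 and Adam8 were also chosen after their values were seen. Of 13 tested glutathione transferase genes, 5 were higher and 0 lower, with a median log2 fold change of 0.64, and besides Gsta4, Gstt1 and Gstt2 these were Gstt3 (12.5% of its words shared with other genes), from 0.84 ± 0.45 to 6.99 ± 2.95 CPM, and Gstp2 (54.3% shared), from 9.31 ± 2.85 to 18.6 ± 3.75 CPM (n = 3). The reads of Gstt3 and Gstp2 are therefore uncertain. Of 16 tested protocadherin gamma genes, 6 were higher and 0 lower, among them Pcdhga10, from 2.94 ± 0.86 to 13.9 ± 1.15 CPM, and Pcdhgb7, from 2.17 ± 1.31 to 13.5 ± 1.68 CPM. Their transcripts share 3′ exons (44.4% and 45.9% of the words of these genes lay in other genes), so the gene each read came from is uncertain, while Pcdhgc3 stood at 144 ± 16.2 and 148 ± 10.9 CPM.

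Genes raised in KO cells lay next to each other. Of the 249, 43 formed 25 pairs of consecutive tested genes on 13 chromosomes. Examples were Ddt, Gstt3, Gstt1 and Gstt2 on chromosome 10, Cbr3, Dop1b and Morc3 on chromosome 16, and Fkbp11, Arf3 and Wnt10b on chromosome 15. In 10000 permutations of the calls over tested genes, the mean was 5.52 pairs and the highest 16 (permutation p = 0.0001, the smallest they can give). The 69 lower genes formed 1 pair (mean 0.43). These permutations tested random placement only, and did not keep together neighbours alike in sequence or expression. Overlapping genes, such as the protocadherin gamma genes Pcdhgb6 and Pcdhga10, were among the 25 pairs. Shared reads from the same strand, as the whole cause, were argued against by 13 pairs. In these, both genes shared under 5% of their words with any other gene (permutation p = 0.0044 against pairs of any kind). The 13 did not exceed the bound of 16, set before that count was made but after the pairs had been listed. A part played by shared reads thus cannot be told apart. Words were compared on the transcript strand, so exons that overlap on opposite strands were not covered. Gm16201 and Adam8, which overlap in this way, were among the 13 pairs. Reads running on from 1 gene into the next stay open too, since 4 pairs lay on opposite strands without overlap against a permuted mean of 2.4 and a highest of 10. The 436 uncalled genes next to raised ones had a median log2 fold change of 0.037 against -0.001 for the 10439 others (permutation p = 0.0419). The shift was small, and leaving out called genes holds it down. Its permutations also did not keep together neighbours alike in expression, so they cannot name a cause. An effect of Setdb1 loss on neighbouring genes together stays open, as untested.

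Control library 3 and KO libraries 2 and 3 held neutrophil transcripts, with 2760, 927 and 334 counts of S100a8, 3244, 972 and 452 of Ngp and 739, 691 and 87 of Mpo, while the other 3 libraries held at most 6 of each. Control library 3 alone also held Xist (112 counts, against 0 to 8 elsewhere), beside Y-linked transcripts found in all 6 libraries, and most of the Cxcl13 (143 counts) and Ccl21a (41 counts). At the ratio of Xist to S100a8 and S100a9 in control library 3, KO libraries 2 and 3 would hold about 49.0 Xist counts together (95% Poisson range 36 to 63), and they held 6, but this assumes 1 source, so whether Xist came with the neutrophils of control library 3 cannot be told apart. A single source of RNA spread over the 3 libraries would keep 1 ratio of Mpo to S100a9, but it was 0.217, 0.657 and 0.226, 3.03 times as high in KO library 2 as in control library 3 (Fisher's exact test, p = 2.3e-67, for counting error only, beside a typical spread between replicates of 16.5% per gene), while control library 3 and KO library 3 gave p = 0.75, so a source common to those stays open. Elane (350, 260 and 54 counts) and Prtn3 (153, 126 and 18 counts) were also held by control library 3, KO library 2 and KO library 3, in this order. Neutrophils or their precursors carried into separate samples may be a source (how the cells were sorted is not given in the sources used here). The maturity of these cells, and whether it changed the ratio of Mpo to S100a9, was not tested. Few red cell transcripts came with them, as the globin gene Hba-a1 had 2 counts in control library 3 and 0 elsewhere. No biological explanation was tested, since both groups held such libraries.

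KO library 1 held counts in 30363 genes against 18737 to 19951 in the other 5. Per library total, without TMM factors, it had 1009 CPM in olfactory and vomeronasal receptor genes, which are silent in most tissues, against 52.5 to 81.7 in the others, and 25575 counts of the predicted gene Gm10800 against 2265 to 8467. Release of silent genes by loss of Setdb1 would raise all 3 KO libraries. KO library 2, at 52.5, lay below the controls (54.9 to 64.6), and KO library 3, at 81.7, lay above them. A release of the size seen in KO library 1 was thus absent from the other KO libraries, while a smaller rise in KO library 3 stays open. Genomic DNA of a male animal may be a source, since genes with at most 1 count in the other 5 libraries had an X chromosome rate per exonic kilobase 0.495 times the autosomal rate (95% bootstrap interval 0.42 to 0.575), near the single X copy of a male, a test chosen before that rate was computed.

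The real split of the 6 libraries gave 318 changed genes and the highest of the other 9 gave 4. Of the 10 splits 1 gave as many, and 10 are too few for a share under 0.05. Nnt was counted under a pair of gene identifiers. Under one of them, control libraries 1 and 2 had 71 and 36 counts and the other 4 libraries 0 to 4. Under the other, control libraries 1 and 2 had 0 and 7 counts against 47 to 62. Control library 3 thus lay with all KO libraries, so Nnt divided the libraries partly along the groups. Whether the animals differed genetically in more than Setdb1 was not tested. A part of such a difference in the 318 calls, or in the raised neighbouring genes, cannot be told apart from loss of Setdb1.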
